A study of Mus musculus with 4 samples.

How the data were processed

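The data were 4 Affymetrix-type oligonucleotide arrays, 2 of control and 2 of mutant memory P14 CD8 T cells from mouse spleen. Per the labels' protocols, CD8 T cells were enriched by negative selection and sorted by flow cytometry, total RNA was isolated with Trizol and a column kit, and biotin-labelled material was hybridised after amplification. The deposited values are MAS5 signal intensities on a linear scale, per the submitters' processing notes, with the version of MAS5 not given in the sources used here. The intensities themselves show the scaling, since the mean after trimming 2% on each side was 250 on every array. MAS5 scales each array by 1 factor, so an array with another shape of its signal distribution keeps that difference. It also subtracts mismatch probe signals, which makes low signals noisy. Detection calls were not used here. The groups were taken from the genotype given for each sample. Nothing in the labels says whether the 2 samples of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical. The labels used here do not give the strain background of the mice or whether the groups were littermates. No 2 arrays held identical values.

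Probe sets were named through the platform's annotation table. Of 45101 probe sets, 64 controls were left out. Of the other 45037, 34945 had 1 gene symbol, 932 had several and 9160 had no gene named here; 0 symbols changed when updated through the gene identifiers of the GRCm38.p6 gene table. No gene was named from a probe set with several symbols. The build of the array's own annotation is not given in the sources used here, so the GRCm38.p6 table was used only for chromosome and gene order.

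Signals were transformed as log2(signal + 32), with no further normalization. Probe sets with a mean log2 value above the 40th percentile were kept (a signal of about 18.0), which left 27022 probe sets of 12263 genes. Mutant was compared with control by limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend on the signal level), with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences are mutant minus control on this scale, which understates the change of low genes. Errors are limma's standard errors where a log2 difference is given and standard deviations of the signal where group means are given.

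Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, on 1 probe set per gene, with adjustment over the lists. The plan was the probe set with the highest mean. By a fault in the selection, means were matched to the wrong probe sets, so the one used need not be the highest. For Hspa1b it was not. List medians, counts of members and the values of named members rest on the probe sets used. Camera with an estimated correlation and fry were run beside it. Of 34 lists, covering T cell programmes, handling signs, other cell types and the neighbours of Zbtb7b, 33 had at least 5 measured members and were tested. At the preset correlation 5 lists passed and with an estimated correlation 0 did. At an unadjusted camera p under 0.05, 7 and 2 did. With the mean of all probe sets of a gene, which needs no selection, the same 5 lists passed at the preset correlation. The immediate-early list then passed too. The estimated correlation was 0.47 for the ribosomal and 0.26 for the terminal effector list. It was 0.0053 for heat shock, -0.023 for NK cell markers and -0.093 for gamma-delta markers, below the preset 0.01. For these lists the loss of the call thus does not show correlated members. With an estimated correlation camera rests on the few residual degrees of freedom of 4 arrays, so few lists can pass. With fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, 0 lists passed (lowest adjusted p = 0.461) and 2 had an unadjusted p under 0.05. For each list the number of members past the threshold was counted over all genes tested and adjusted over the list alone.

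The lists, the limma, camera and fry tests and the rule for named genes were fixed before the data were examined. The rule named every probe set of Zbtb7b, the 12 genes with the largest rise and the 12 with the largest fall past the threshold, and up to 4 members with the largest difference of each list described. It also named 10 genes of interest whatever their values (Cd4, Cd8a, Cd8b1, Runx3, Gzmb, Il2, Ifng, Il7r, Nfatc2 and Zbtb32). Since fewer than 12 genes per direction passed, each direction was filled up with the genes of smallest p among those at least 2-fold apart with no overlap, and these are given as not past the threshold.

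Alternatives were other pseudocounts (8 and 128), no filter and a filter at the 60th percentile, quantile normalization, centring each array on its median, eBayes without a trend, the replicate number as a block, and leaving out each array in turn. For lists, the mean of all probe sets of a gene was another. Where an array was left out, the lone array of its group was assumed to vary like the other group. Added after the data were examined were array weights, the heat shock list without Hspa1a and Hspa1b, and the count of named probe sets moved by leaving out 1 array. So were the test of placement along the chromosomes, also under other settings, those of the other probe sets of Pdk1, Rbms1 and Tanc1 and of one direction, and the look at probe sets with several genes near Zbtb7b. With 2 arrays per group the array weights are forced to be equal within a group (1.86 for both control and 0.54 for both mutant arrays), so they cannot weigh mutant replicate 1 down against mutant replicate 2. The limma procedure was tested on simulated values for the same 27022 probe sets, 2 arrays against 2. It recovered 18% of the probe sets changed 2-fold, 80% of those changed 4-fold, 98% of those changed 8-fold and 100% of those changed 16-fold (50 each), and called 6 unchanged ones. The list test called the 1 shifted list and 0 of 10 unchanged lists. In these simulations probe sets varied independently, each with the same spread on all 4 arrays, and the lists were random genes. They hold no array that stands apart and no correlated list members, so the rates may not apply to the real arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the positional tests and the plots.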

Results

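Gene expression was measured in memory CD8 T cells of mouse spleen on 4 oligonucleotide arrays, 2 from cells with wild-type ThPOK (control) and 2 from cells carrying a mutated ThPOK (mutant). The cells were P14 T cells, which carry a transgenic T cell receptor specific for a peptide of the lymphocytic choriomeningitis virus (LCMV) glycoprotein. They were sorted from spleen more than 100 days after infection with that virus. ThPOK, encoded by Zbtb7b, is a zinc finger transcription factor best known for directing thymocytes to the CD4 helper lineage. The HD (helper-deficient) mutation that the mutant samples are named for changes the protein, so the transcript level does not check the genotype labels. The comparison of the 2 groups asked which genes ThPOK regulates, directly or through other genes, in CD8 T cells. Each array gave 1 signal per probe set, with no count behind it, so the number of arrays limits the precision. Median signals were 26.6 and 27.0 on the control arrays, 44.5 on mutant replicate 1 and 26.5 on mutant replicate 2. Mutant replicate 1 correlated with the other arrays at no more than 0.968 over probe sets, and the other 3 arrays with each other at 0.987 or more; probe sets are not independent replicates.

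Transcripts of Zbtb7b itself were low on all 4 arrays and did not differ between the groups beyond the spread between replicates. Its first probe set had a signal of 83.3 ± 16.0 in control and 60.4 ± 35.0 in mutant cells (mean ± SD, n = 2 each), a log2 difference of -0.37 ± 0.31 (SE, limma adjusted p = 0.877). Its second probe set went the other way, from 38.2 ± 26.3 to 75.0 ± 45.7, a log2 difference of 0.59 ± 0.38 (limma adjusted p = 0.877). Per array, in the order control 1, control 2, mutant 1 and mutant 2, the signals were 72.0, 94.6, 35.6 and 85.2 for the first probe set and 56.8, 19.6, 107 and 42.7 for the second. Without mutant replicate 2 both probe sets passed the threshold in opposite directions, at log2 differences of -0.76 and 1.04, and without mutant replicate 1 the first one stood at 0.030. Of the 80 annotated genes lying next to Zbtb7b on chromosome 3 in the GRCm38.p6 gene order, 44 were measured. Their median log2 difference was 0.14, 28 were higher and 16 lower, none passed the threshold, and 2 had an unadjusted limma p under 0.05 (list adjusted p = 0.753 by camera). One called probe set that matches several genes, which are therefore not named, lay 42 to 44 genes from Zbtb7b, just outside this neighbourhood. Its signal was 225 ± 6.82 in control and 22.0 ± 12.9 in mutant cells (log2 difference -2.27 ± 0.25, limma adjusted p = 0.0253).

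On the log2(signal + 32) scale the largest rise in mutant cells was that of Erdr1, an erythroid differentiation regulator, from a signal of 89.1 ± 16.3 to 3350 ± 164 (SD, n = 2 each). The T cell receptor gamma variable genes Trgv1 and Trgv4, segments of one chain of the gamma-delta receptor, rose from near the floor of the array. Trgv1 went from 14.5 ± 16.9 to 494 ± 80.4 and Trgv4 from 12.4 ± 14.9 to 269 ± 95.4. The inducible heat shock protein genes Hspa1b and Hspa1a, which encode near-identical Hsp70 chaperones, fell from 3568 ± 143 to 139 ± 89.8 and from 689 ± 23.3 to 41.3 ± 6.33. No fold is given where a group has a signal under 100, close to the floor of the array. Dapl1, a gene of the death-associated protein family and a member of the memory precursor and naive-associated list, fell from 783 ± 105 to 131 ± 38.8 (5.97-fold lower).

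The other genes past the threshold were the RNA-binding protein gene Rbm45, which fell from 590 ± 78.8 to 158 ± 4.42, and the predicted gene Gm6958, which fell from 241 ± 5.80 to 51.2 ± 11.1. On the log2(signal + 32) scale the differences were 4.81 ± 0.17 for Erdr1 (SE, limma adjusted p = 3.27e-05), 3.54 ± 0.28 for Trgv1 (adjusted p = 0.00416) and 2.76 ± 0.32 for Trgv4 (adjusted p = 0.0344). They were -4.50 ± 0.31 for Hspa1b (limma adjusted p = 0.00217), -3.30 ± 0.19 for Hspa1a (adjusted p = 7.22e-04) and -2.34 ± 0.21 for Dapl1 (adjusted p = 0.00853). For Rbm45 the difference was -1.71 ± 0.18 (limma adjusted p = 0.0221) and for Gm6958 -1.72 ± 0.21 (adjusted p = 0.0493). This scale understates the change of low genes. Each of these genes lay on the same side in both mutant arrays against both control arrays. In the GRCm38.p6 gene order Hspa1a and Hspa1b lie on chromosome 17, Trgv1 and Trgv4 on chromosome 13, Dapl1 and Rbm45 on chromosome 2, Gm6958 on chromosome 16 and Erdr1 on chromosome X. Dapl1 and Rbm45 shared a stretch of 100 consecutive measured genes with Tanc1, Rbms1 and Pdk1, which also had an unadjusted limma p under 0.001. All 3 probe sets of Hspa1b passed, at log2 differences of -4.50, -4.40 and -4.03. The probe sets of Hspa1a and Hspa1b, and those of Trgv1 and Trgv4, may catch transcripts of related genes, so the share of each gene in these changes is uncertain. Probe sequences were not examined. A second probe set of Trgv4 gave 2.27 ± 0.31 and did not pass (limma adjusted p = 0.0867).

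**Figure D1:**
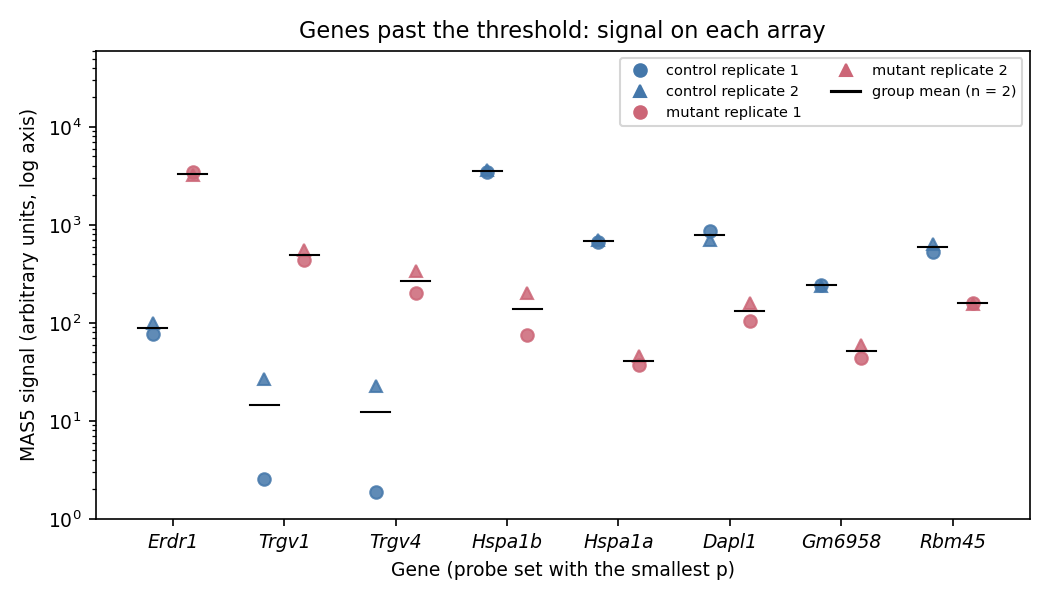
Signal of each of the 4 arrays (MAS5 arbitrary units, log axis) for the 8 named genes past the threshold, each by its probe set of smallest p, with control arrays in blue, mutant arrays in red and a bar at each group mean (n = 2). Erdr1, Trgv1 and Trgv4 lie higher in both mutant arrays (Erdr1 at 3234 and 3466 against 77.6 and 101), and the other 5 genes lie lower in both.

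In total 15 of 27022 probe sets passed an adjusted p of 0.05, 7 higher and 8 lower in mutant cells. Of these, 10 belonged to 1 gene each and named 8 genes, 2 matched several genes and 3 had no gene named here. An unadjusted limma p under 0.05 was reached by 1144 probe sets, where chance alone gives 1351. Without regard to any test, 124 probe sets were at least 2-fold apart with no overlap of the groups, 96 higher and 28 lower. After quantile normalization this split was 66 and 37, and with each array centred on its median 67 and 33. Groups did not overlap for 35.6% of the probe sets tested, where chance gives 33.3% for 2 arrays against 2. An exact permutation test of 2 against 2 cannot give a two-sided p below 0.333, so every p here rests on limma's pooled spread. The count of calls moved strongly with single arrays. It was 38 without control replicate 1, 57 without control replicate 2, 62 without mutant replicate 1 and 4742 without mutant replicate 2, with the 15 probe sets among the calls each time. The 2-fold count was 219, 335, 97 and 1402 in the same order. With a spread prior that does not follow the signal level, 3 of the 15 passed. Over 13 settings, array weights left out, Erdr1 and Hspa1a passed in 13, Hspa1b, Trgv1, Dapl1 and Rbm45 in 12, and Gm6958 and the Trgv4 probe set in 7.

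Further genes were at least 2-fold apart, lay on one side in both mutant arrays and did not pass the threshold. Ets1, a transcription factor of lymphocyte development, had signals of 578 ± 72.2 in control and 175 ± 36.5 in mutant cells (SD, n = 2 each; log2 difference -1.57 ± 0.20, limma adjusted p = 0.0534). Pdk1, a kinase that inhibits pyruvate dehydrogenase, had 7.81 ± 10.2 and 144 ± 11.7 on its probe set of smallest p (log2 difference 2.17 ± 0.28, limma adjusted p = 0.0580). The 3 other kept probe sets of Pdk1 were brighter and differed less, at 0.27, 0.52 and 0.97. Their mean log2 values were 8.47, 10.6 and 10.2 in the same order. The low control signal thus holds for that probe set and not for Pdk1 as a whole. Tanc1, a scaffold protein gene, had 53.6 ± 18.4 and 272 ± 48.5 (1.84 ± 0.24, limma adjusted p = 0.0580), and C130026I21Rik had 14.5 ± 5.47 and 161 ± 34.0 (2.05 ± 0.26, limma adjusted p = 0.0534). The T cell receptor beta variable gene Trbv13-2 stood at a log2 difference of 1.68 (limma adjusted p = 0.153) and the nucleic acid-binding protein gene Rbms1 at 1.07 (adjusted p = 0.174). Lxn, a carboxypeptidase inhibitor, stood at -1.07 and Iftap at -1.26 (limma adjusted p = 0.239 for both). The rest had limma adjusted p-values between 0.484 and 0.659. Log2 differences above 0 were those of Dclk2 (1.42), Prss2 (1.46), 4930581F22Rik (1.41) and the lipid antigen-presenting gene Cd1d2 (1.45). Like Trbv13-2 (18.3), these genes had mean control signals of 19.9 or less, close to the floor of the array. Log2 differences below 0 were those of Nebl (-1.23), the cAMP-responsive transcription factor Crem (-1.03), the RNA helicase Ddx39b (-1.01) and Mpzl3 (-1.03).

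Among gene lists fixed before the data were examined, the heat shock and unfolded protein response list was lower in mutant cells. Of its 23 measured genes 18 were lower and 5 higher (median log2 difference -0.21, camera adjusted p = 8.45e-07; adjusted p = 0.752 with an estimated correlation). Hspa1b and Hspa1a passed over all genes tested. Adjusted over the list alone 4 genes fell, these 2 with the cochaperone Dnajb1 (-1.04 ± 0.25) and the chaperone Hsph1 (-0.84 ± 0.21). Xbp1, a transcription factor of the unfolded protein response, had a log2 difference of 1.00 ± 0.43 and did not pass. It stood at 0.38 without mutant replicate 1 and at 1.62 without mutant replicate 2. With Hspa1a and Hspa1b taken out, a check added after the result was seen, the median was -0.15 and camera's adjusted p 0.00252. This check was run at the preset correlation only. The list passed at the preset correlation without each array in turn, with a median from -0.37 without mutant replicate 2 to -0.14 without control replicate 1.

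The gamma-delta T cell marker list was higher, with all 5 measured of 17 genes higher in mutant cells (median log2 difference 0.41, camera adjusted p = 1.03e-04; adjusted p = 0.752 with an estimated correlation). The median was 0.71 without mutant replicate 2, 0.70 without control replicate 2 and 0.32 without mutant replicate 1. With the mean of all probe sets of a gene the list's median was 0.31 (camera adjusted p = 2.08e-04 at the preset correlation). In the main test each gene entered by 1 probe set, not reliably the one of highest mean. For Trgv4 this was the probe set that did not pass over all genes tested, so 1 member, Trgv1, is counted as past that threshold, while Trgv1 and Trgv4 rose when adjusted over the list alone. The scavenger receptor gene Cd163l1 had a log2 difference of 0.41 ± 0.27 and the transcription factor gene Sox13 0.22 ± 0.32, and neither passed. Il17a stood near the floor, at 24.5 ± 21.6 in control and 33.7 ± 32.8 in mutant cells. With no filter on dim probe sets the list did not pass (camera adjusted p = 0.0893), and with the filter at the 60th percentile it had too few measured genes to test.

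Lists of terminal effector genes and natural killer (NK) cell markers were lower, at camera adjusted p = 0.00777 and 0.00913; both lost the call with an estimated correlation (adjusted p = 0.854 and 0.850). Of 21 measured terminal effector genes 13 were lower and 8 higher (median log2 difference -0.07, mean -0.27), and of 13 NK cell markers 9 were lower and 4 higher (median -0.21). No member of either list passed the threshold, over all genes or adjusted over the list alone; at an unadjusted limma p under 0.05, 4 terminal effector genes and 2 NK cell markers were lower. The largest differences were those of the granule protease genes Gzma (-1.31 ± 0.64) and Gzmb (-0.85 ± 0.33), the NK receptor gene Klre1 (-1.26 ± 0.41) and the membrane protein gene Emp1 (-1.11 ± 0.28). With 1 array left out these ranged from -2.46 to -0.16 for Gzma, -1.33 to -0.37 for Gzmb, -1.81 to -0.70 for Klre1 and -1.58 to -0.64 for Emp1. The smaller difference came without mutant replicate 2 for Gzma and Gzmb, without mutant replicate 1 for Emp1 and without control replicate 1 for Klre1. Among NK cell markers the receptor gene Klra8 stood at -0.52 ± 0.27 and the signalling adaptor gene Tyrobp at -0.50 ± 0.19. Of the 13 measured NK cell markers 10 are also held by another list, Gzma and Klre1 by the terminal effector list. Terminal effector genes had a median of 0.0019 in mutant replicate 1 and -0.37 in mutant replicate 2 against the control mean. Their list did not pass without mutant replicate 2 (camera adjusted p = 0.407), without control replicate 1 (0.0528), after quantile normalization (0.0827), with no filter (0.0939) or with a filter at the 60th percentile (0.0759). The NK cell marker list did not pass without mutant replicate 2 (camera adjusted p = 0.407), with no filter (0.238) or with a filter at the 60th percentile (0.0513).

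Ribosomal protein genes were higher as a list, with 32 of 35 measured genes higher (median log2 difference 0.36, camera adjusted p = 9.18e-05; adjusted p = 0.854 with an estimated correlation). None of them passed singly, over all genes or over the list alone, and 0 had an unadjusted limma p under 0.05. The difference lay in mutant replicate 1, where the list's median was 0.72 above the control mean against 0.036 in mutant replicate 2. Rpsa, a component of the small subunit, had signals of 21481 and 20501 in control cells and 44973 and 20899 in mutant replicates 1 and 2. Without mutant replicate 1 the list did not pass (camera adjusted p = 0.268), nor after quantile normalization (median 0.043, camera adjusted p = 0.307) or with no filter on dim probe sets (median 0.34, camera adjusted p = 0.389). On that array the 100 brightest probe sets held 16.2% of the signal, against 9.54% to 9.75% on the other 3.

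**Figure D2:**
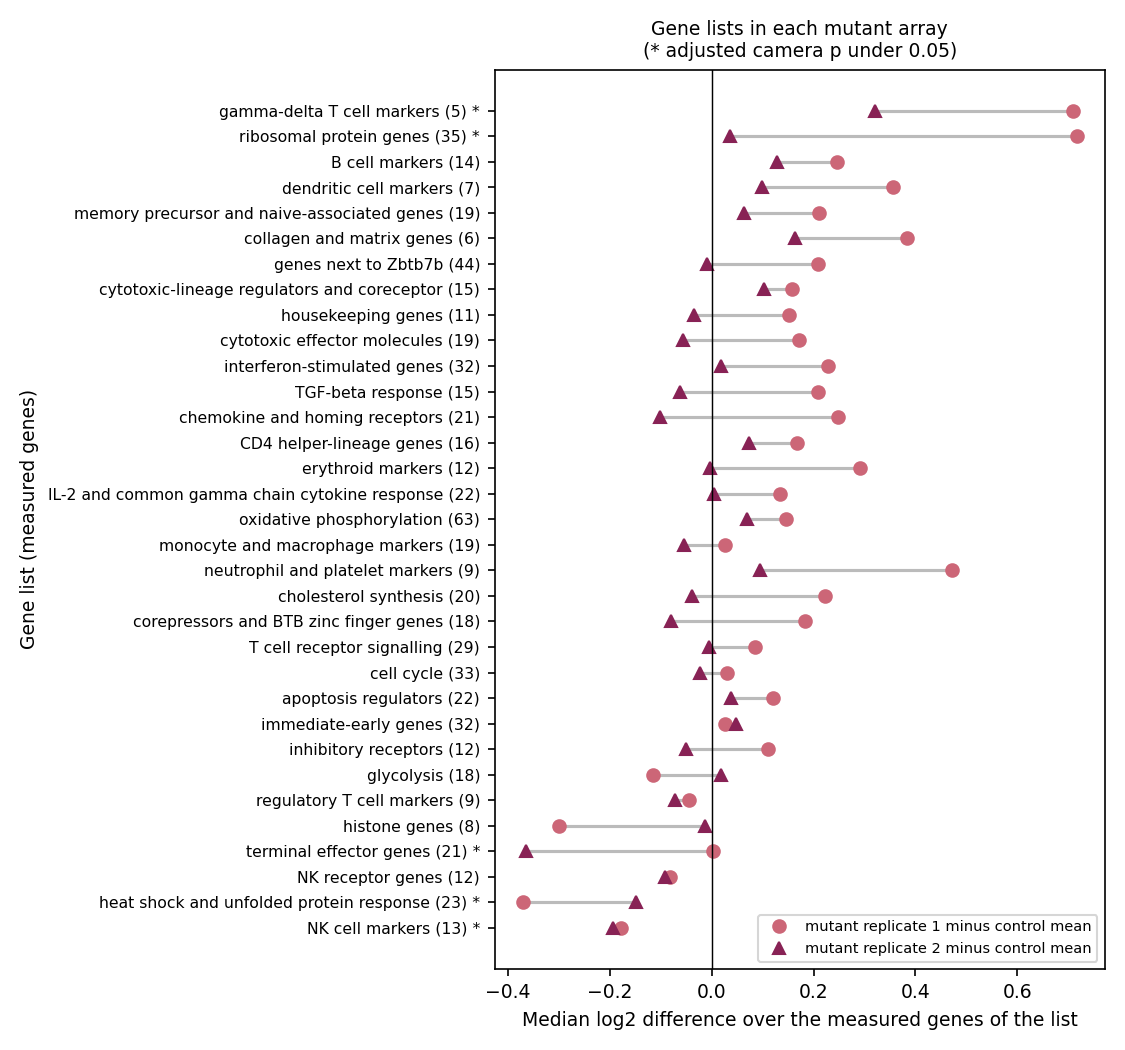
Median log2 difference of each gene list in mutant replicate 1 (circles) and mutant replicate 2 (triangles) against the mean of the control arrays, with the number of measured genes in brackets and a star where camera's adjusted p was under 0.05 at the preset correlation. The ribosomal list lies at 0.72 and 0.036, the terminal effector list at 0.0019 and -0.37, and the heat shock list below 0 on both arrays.

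The genes that separate the cytotoxic and helper lineages showed no change past the threshold. Cd8a, the coreceptor chain of cytotoxic T cells, had log2 differences between -0.06 and 0.25 over 5 probe sets, and Cd8b1 0.25 ± 0.18. Runx3, a transcription factor of the CD8 lineage that acts against ThPOK expression, stood at -0.19 ± 0.16. Both probe sets of Cd4 fell below the filter, with signals of 15.3 or less on all 4 arrays. Of 15 measured cytotoxic-lineage regulators and coreceptors 0 passed and 0 had an unadjusted limma p under 0.05 (median 0.14, camera adjusted p = 0.711). Id2 stood at 0.33 and Eomes, a T-box factor of memory CD8 T cells, at 0.30. Of 16 measured CD4 helper-lineage genes 0 passed and 1 had an unadjusted limma p under 0.05 (median 0.12, camera adjusted p = 0.920). In that list the repressor gene Bcl6 stood at -0.73 ± 0.28 and Cd40lg, the helper ligand of CD40, at 0.52 ± 0.39. Without mutant replicate 1 they stood at -0.28 and 0.068, and without mutant replicate 2 at -1.17 and 0.96. A median above 0 stood there beside a test direction of lower. Camera compares the test statistics of a list with those of the other genes, so its direction need not follow the median. The median log2 difference over all probe sets tested was 0.061, and -0.010 after quantile normalization. Probe sets as a whole thus stood slightly above 0 before that normalization. Why the test direction and the median differ for this list was not tested.

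No single effector or memory gene other than Dapl1 passed the threshold, while the terminal effector list passed as lower at the preset correlation (camera adjusted p = 0.00777) and not with an estimated one (0.854). Of 19 measured cytotoxic effector molecules 0 passed and 4 had an unadjusted limma p under 0.05 (median 0.13, camera adjusted p = 0.711). The chemokine gene Ccl5 stood at 0.58 ± 0.37, and at -0.058 without mutant replicate 1, and the granzyme gene Gzmm at 0.55 ± 0.16. Gzmb, at 2146 ± 782 in control and 1199 ± 557 in mutant cells (SD, n = 2 each), had a limma adjusted p of 0.877. The interferon gamma gene Ifng stood at -0.32 ± 0.26 and, without control replicate 1, at 0.088. Il2 was below the filter, with signals between 9.07 and 25.9. Of 19 memory precursor and naive-associated genes 1 fell, Dapl1, while the cytokine signalling inhibitor Socs3 stood at 0.63 ± 0.22 and Lef1 at 0.50 ± 0.27 (median 0.18, camera adjusted p = 0.545). Il7r, the receptor chain for a survival cytokine of memory cells, had log2 differences of 0.41 ± 0.30 and -0.00087 ± 0.17, and of -0.043 and 0.031 after quantile normalization. Nfatc2, a transcription factor downstream of the T cell receptor, stood at 0.33, -0.25 and 0.13 over 3 probe sets, the last at -0.042 after quantile normalization. Zbtb32, a relative of ThPOK, stood at 0.11 ± 0.38 and at -0.042 after that normalization.

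Lists of activation and migration genes did not pass either with all 4 arrays, the planned filter and 1 probe set per gene. Of 32 measured immediate-early genes 16 were higher and 16 lower, and 0 passed (camera adjusted p = 0.536). At an unadjusted limma p under 0.05, 1 was higher and 4 were lower. The median was 0.0012 and the mean -0.0097, with a test direction of lower. The list passed as lower with no filter on dim probe sets (camera adjusted p = 0.0393) and with the mean of all probe sets of a gene (0.0377), each at the preset correlation; with an estimated one and the planned filter its adjusted p was 0.854. The phosphatase gene Dusp1 stood at -1.12 ± 0.34, Fosb at -1.06 ± 0.35 and Fos at -0.99 ± 0.30, while the inhibitor of NF-kB Nfkbia stood at 1.23 ± 0.65 and at -0.035 without mutant replicate 1. Dusp1 ranged from -1.69 without mutant replicate 2 to -0.55 without mutant replicate 1, Fos from -1.48 to -0.50 without the same arrays, and Fosb from -1.59 without control replicate 2 to -0.54 without control replicate 1. Of 21 chemokine and homing receptors 0 passed and 4 had an unadjusted limma p under 0.05. Their median was 0.13 beside a test direction of lower (camera adjusted p = 0.711), and -0.0066 after quantile normalization. Without mutant replicate 1 the list passed as lower at the preset correlation (median -0.10, camera adjusted p = 0.0354); with all 4 arrays and an estimated correlation its adjusted p was 0.905. The adhesion receptor gene Cd44 stood at 0.71 ± 0.17, Cx3cr1 at -0.62 ± 0.25 and Cxcr4 at -0.59 ± 0.24. Without mutant replicate 1 Cx3cr1 stood at -0.93 and Cxcr4 at -0.24, and without mutant replicate 2 at -0.31 and -0.94. Of 32 interferon-stimulated genes 21 were higher and 0 passed (median 0.13, camera adjusted p = 0.545). At an unadjusted limma p under 0.05, 4 were higher and 0 lower. The antiviral synthetase gene Oas2 stood at 0.79 ± 0.31 and the proteasome subunit gene Psmb8 at 0.52 ± 0.21.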

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

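The bacterial and phage transcripts that are added to every sample before hybridisation, a measurement outside the comparison of the groups, were brighter on mutant replicate 1. Over their 18 probe sets the median signal was 2.91 times the control mean on mutant replicate 1, against 1.09 times on mutant replicate 2. The control arrays themselves stood at 0.934 and 1.07. All 18 probe sets were highest on mutant replicate 1, by 2.38 to 3.31 times over the next array. No biological explanation was tested, since the added transcripts do not come from the cells. The same array had the highest median signal (44.5 against 26.5 to 27.0) and the highest maximum (57950 against 27747 to 28265). The spread within the mutant group was wider than within the control group, with a median standard deviation of 0.22 against 0.12 on the log2 scale.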

How the results depend on the processing

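Array weights, the heat shock list without its 2 called genes, the positional test under other settings and the count of named probe sets moved by leaving out 1 array were chosen after the results were seen. Of 15 calls, 13 remained at either other pseudocount, 10 with no filter, 12 with the filter at the 60th percentile, 12 after quantile normalization (of 13 calls) and 15 after median centring (of 18). Array weights gave 22 calls, the 15 among them, but 2 arrays per group force equal weights within a group (1.86 for control, 0.54 for mutant), so this does not test the array that stands apart. Without a trend 3 probe sets passed, and the cause was not tested. Leaving out 1 array gave between 38 and 4742 calls; the lone array of its group was then assumed to vary like the other group. The count at least 2-fold apart was 823 with a pseudocount of 8, 32 with the larger one and 69 with the filter at the 60th percentile, as the pseudocount and the filter act on dim probe sets, and 97 to 1402 with 1 array left out. The lists past the threshold were 5, and 2 with no filter (heat shock and immediate-early), 3 with the filter at the 60th percentile (heat shock, ribosomal and oxidative phosphorylation), 0 with an estimated correlation and 3 to 7 with 1 array left out; the cause was not tested. The probe set that stood for a gene in the lists could also change with the filter, the pseudocount and the normalization. Over the probe sets, the replicate 1 minus replicate 2 differences of the 2 groups correlated at 0.02. Mutant replicate 1 stands apart, so this value cannot show whether the samples were paired. With the replicate block 43 probe sets passed, among them the 15. After quantile normalization the log2 differences of Il7r turned to -0.043 and 0.031, of 1 of 3 Nfatc2 probe sets to -0.042 and of Zbtb32 to -0.042, none past the threshold; the cause was not tested. With 1 array left out the Zbtb7b probe sets ranged from -0.76 to 0.030 and from 0.14 to 1.04, and the median of its neighbours from -0.0099 to 0.21. Leaving out 1 array moved 0 of the 8 named probe sets past the threshold by over 1.5 times, and 43 of the 69 named ones not past it. The 8 were called for differences large against their spread, which makes such a move unlikely. Some of the 69 had differences near 0, where it is easily reached. The contrast thus follows largely from the selection and is no evidence of robustness. Other differences that changed sign with 1 array left out, none called with all 4 arrays, ranged from -0.12 to 0.26 and -0.75 to 1.07 for 2 probe sets of Cd8a, -0.73 to 0.088 for Ifng, and -0.027 to 0.85 and -0.11 to 0.11 for Il7r. They ranged from -0.078 to 0.33 for Nfatc2, -0.36 to 0.57 for Zbtb32, -0.058 to 1.23 for Ccl5, -0.035 to 2.49 for Nfkbia, -0.0060 to 1.10 for Rpsa and -0.035 to 0.48 for Sox13. Fewer arrays are the only change there. Signals near the floor limit what can be said of Zbtb7b, Cd4, Il2 and the control level of Trgv1 and Trgv4.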

Other observations

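The tests of placement along the chromosomes, of the other probe sets of Pdk1, Rbms1 and Tanc1, and of one direction were chosen after the results were seen; those on heat shock targets, on the neighbours of Hspa1a and Hspa1b and on other gamma-delta markers were written before theirs.

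Metabolic and growth lists did not pass at the preset correlation. Of 63 measured oxidative phosphorylation genes 50 were higher in mutant cells (median log2 difference 0.10, camera adjusted p = 0.236). That list passed without mutant replicate 1 (median 0.068, camera adjusted p = 0.00766), after quantile normalization (0.009996) and with the filter at the 60th percentile (0.0315), each at the preset correlation. With an estimated correlation on all 4 arrays its adjusted p was 0.854. Camera's adjusted p was 0.545 for glycolysis and for cell cycle genes, 0.652 for cholesterol synthesis, 0.406 for histone genes, 0.733 for apoptosis regulators and 0.753 for housekeeping genes. NK receptor genes, 7 lower and 5 higher of 12, had a median of -0.13 (camera adjusted p = 0.0601). They passed as lower without control replicate 2 (camera adjusted p = 3.63e-04), without mutant replicate 1 (0.00182), after quantile normalization (0.0404), at the smaller and the larger pseudocount (0.0252 and 0.0230) and with the replicate block (0.0109), each at the preset correlation. With an estimated correlation on all 4 arrays their adjusted p was 0.854. Signalling lists gave camera adjusted p = 0.842 for T cell receptor signalling, 0.753 for the interleukin 2 and common gamma chain cytokine response, 0.922 for the TGF-beta response, 0.711 for inhibitory receptors and 0.711 for corepressors and BTB zinc finger genes. In 11 of the 33 lists the test direction differed in sign from the median or the mean; all 11 were tested as lower, and none passed.

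Lists of other cell types gave no call apart from the NK cell marker and gamma-delta lists, which passed at the preset correlation only. Camera's adjusted p was 0.650 for B cell markers (median 0.20, and -0.024 after quantile normalization), 0.650 for monocytes and macrophages, 0.536 for dendritic cells, 0.650 for neutrophils and platelets, 0.650 for regulatory T cells, 0.885 for erythroid markers and 0.609 for collagen and matrix genes. The neuropilin gene Nrp1, singled out after its values were seen, was lower when adjusted over the regulatory T cell list alone (log2 difference -0.83 ± 0.21). The haemoglobin gene Hba-a2, also chosen after its values were seen, had signals of 38.4 and 64.9 in control cells, 584 in mutant replicate 1 and 54.6 in mutant replicate 2. The Y-linked gene Eif2s3y had signals of 2968 and 3001 in control and 2103 and 3187 in mutant cells, while Xist, which is transcribed from the inactive X chromosome, stayed at 49.0 or less on all 4 arrays.

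On chromosome 2 (GRCm38.p6 gene order) Dapl1, Tanc1, Rbms1, Pdk1 and Rbm45 lay within 100 consecutive measured genes. They were 5 of 24 genes with an unadjusted limma p under 0.001, against a median of 2 in the densest stretch under random placement (permutation p = 0.0011). Chance alone gives 22.0 kept probe sets with 1 gene symbol under that limma p, a count of probe sets and not of genes. The stretch held the same 5 genes after quantile normalization and with the larger pseudocount (permutation p = 0.000999 each, the smallest that the permutations could give), and 8 genes without mutant replicate 1 (p = 0.00699), but without mutant replicate 2 the densest stretch lay on chromosome X (p = 0.108). A shift of the whole stretch in one direction by 0.5 or more, a bound set after the result, is argued against by the other 95 measured genes of the stretch, whose median log2 difference was 0.14 with a spread of 0.048, with 58 higher and 37 lower, while a smaller shift is not excluded. A base difference under a single probe set is argued against as the whole cause for Pdk1, whose 3 other probe sets stood at 0.27, 0.52 and 0.97 (median 0.52) against 2.17, which leaves it open as part of the cause, and it is left open for Rbms1 and Tanc1, with only 2 others (median 0.45, at -0.0077 and 0.91). A stretch of chromosome 2 from another mouse strain in one group may thus be a candidate explanation, and regulation of these genes by ThPOK is another; neither was tested, since no genotype data were used here.

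Hspa1a and Hspa1b fell together, and stress during handling of the control cells could give the same picture. The other 9 measured targets of heat shock factor had a median log2 difference of -0.33, 8 of them lower. With the spread of that median (0.18) this does not separate from the bound of -0.5 set in advance. Each target entered by 1 probe set, not reliably the one of highest mean, which limits this test further. A variant stretch around the 2 genes also stays open: 1 of 41 measured neighbours, Ddx39b, had an unadjusted limma p under 0.001, and 0.0522 of runs of that length held as many. An effect of ThPOK on these genes was not tested separately and remains open.

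The rise of Trgv1 and Trgv4 could come from gamma-delta T cells among the sorted mutant cells, from transcription of these segments in the P14 cells, or from a strain difference. The 3 other measured gamma-delta markers, Cd163l1, Sox13 and Il17a, had a median log2 difference of 0.22, below the bound of 0.5 set in advance. That bound was wrong for these genes, since all 3 had mean signals under 100, where a small share of such cells would not show. Each was taken by 1 probe set, not reliably the one of highest mean. Sorting of P14 CD8 T cells would remove most other cells, and none of the 5 measured genes of the list is held by another list. These explanations, with an effect of the mutated ThPOK among them, cannot be told apart here.

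One probe set that matches several genes 42 to 44 genes from Zbtb7b passed the threshold as lower in mutant cells (log2 difference -2.27), and of 8 such probe sets within 100 genes it was the 1 with an unadjusted p under 0.001. Among the 86 measured neighbours with a probe set of their own, 0 had a limma p under 0.001, where the observed share over all measured genes gives 0.169. This count thus excludes nothing, and another probe set of the same genes gave 0.31. A segment of another strain around Zbtb7b stays open for this probe set. For the rise of Erdr1 on chromosome X, a strain difference and an effect of the mutated ThPOK were not tested and both stay open.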
